A study of Mus musculus with 2 samples.

How the data were processed

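Total RNA of gastrocnemius muscle from 2 male B6CASTF1/J mice was sequenced in 1 library per animal. Per the labels' protocols, 300 ng of RNA went into a directional kit, with ribosomal RNA reduced and an external (ERCC) spike-in mix added. Each library came with a gene table, a transcript table and a second transcript table. Per the deposited README, all used mm10 with the GENCODE M21 annotation. The gene table and first transcript table were made from transcriptome alignments, and the second transcript table from reads and an index. Per the file headers, the column names are those RSEM writes and, for the second transcript table, those kallisto writes. The aligner, the quantifier versions, the strand setting and the spike-in amounts were not given in the sources used here. Antisense and overlapping genes may therefore share reads.

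The authors' deposited expected counts are estimated reads per gene or transcript, not normalized. The deposited TPM values, a relative abundance scaled by transcript length and library, cover all entries, spike-ins included, per the file headers and their sums. The percent column of the first transcript table, per the file headers, is the share of each transcript in its gene. The tables hold 55536 annotated genes, 96 spike-ins, 1 phage control (phiX) and 26248 entries with numeric identifiers, which held 0 counts. Entries that are not genes stayed out of library sizes and tests.

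Expected counts were rounded to whole numbers for tests. Library sizes were scaled by the trimmed mean of M values (edgeR 4.0.16 in R 4.3.3). Log2 ratios used a prior of 1 count. The 2 libraries differed beyond sampling noise (chi-square per degree of freedom 61.2), so they are not 1 library deposited again. That value cannot tell animals from preparations, and they were kept as 2 animals because the labels number them so. Genes with a mean of 10 or more counts were tested with an exact two-sided conditional binomial test and Benjamini-Hochberg adjustment at 0.05, and genes passing it are described as called. A gene was 2-fold apart when its absolute log2 ratio was 1 or more at a mean of 100 or more counts. Ratios of TPM used an added 0.1 TPM. Dominant transcripts were compared for genes with 2 or more transcripts and 5 or more TPM in both animals, with a Clopper-Pearson interval at 95%.

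Before the data were examined, 51 gene lists, 11 isoform pairs and the rule for named genes were fixed. The rule took the 20 most abundant nuclear protein-coding genes, all pair and myosin genes, and up to 4 members of each other list by TPM plus up to 2 by ratio. It also took the 12 named genes with the largest and 12 with the smallest ratio among tested genes with a mean of 100 or more counts. Isoform genes from a fixed list and the 5 most abundant noncoding genes completed it. A list's median ratio over members with a mean of 10 or more counts was placed among 10000 random lists of the same size, matched on expression in 20 bins. Medians outside percentiles 2.5 to 97.5 are described as outside the random range, a description of these libraries and not a test. Acta2, Tagln, Sln, Xist, Arntl, Npas2, Clock, Id1, Csrnp1, Hist2h2aa1, Gm14760, Gm14288 and Gm5559 lie outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

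Read sharing was measured as the percent of 31-base words of a gene's annotated transcripts that occur on the same strand in no other gene. Trends of ratio on transcript length and GC content were removed by lowess with a fraction of 0.2 and 2 rounds (statsmodels 0.14.6). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were DESeq2 1.42.0 size factors, total counts and spike-ins as scalings, other count and TPM minimums, another prior, an assumed biological variation of 0.1 in edgeR's exact test, the second quantification, other denominators and each animal left out. Total counts, spike-ins and the removed length and GC trend were added for the lists after the data were seen. No allele of either parent strain was separated, since each table holds 1 value per gene.

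The tests were checked on simulated data for 13940 genes. The binomial test called 98% of 50 genes changed to 0.5-fold, 90% of 50 at 1.5-fold, 100% of 50 at 2-fold and 0.0655% of unchanged genes. Of 200 simulated lists that did not move, 6.5% lay outside the random range, and 100% of 50 lists moved by 0.5 did. Counts were drawn with counting noise only, and the changed genes had a mean of 100 or more counts. The simulated lists were random genes with independent noise added. The real libraries differed beyond counting noise and the real lists hold related genes, so these rates do not carry over to them.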

Results

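Total RNA was measured in the gastrocnemius, the large calf muscle, of 2 adult male mice aged 8 to 10 months. Both were of the strain B6CASTF1/J, the first-generation hybrid of C57BL/6J and CAST/EiJ. The labels name 1 group and no treatment, so the design allows the genes expressed in this muscle to be described and its 2 animals to be compared. The labels give the animals different numbers under 1 shared donor identifier. Genes held 36792619 estimated counts in replicate 1 and 37752252 in replicate 2. At this depth 3 counts, the limit that a count of 0 allows, were 0.0815 and 0.0795 CPM (counts scaled to library size). These limits cover counting error only. Values after ± are SDs over 2 animals.

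Among nuclear protein-coding genes, those of contraction and energy supply were the most abundant. Ckm (ENSMUSG00000030399.2, chromosome 7, 19404776 to 19422841 in mm10), which encodes muscle creatine kinase, was the most abundant nuclear protein-coding gene at 17876 ± 831 TPM (SD, n = 2). Acta1 (ENSMUSG00000031972.5, chromosome 8, 123891769 to 123894751), skeletal alpha-actin, followed at 17562 ± 357 TPM. The fast troponin T gene Tnnt3 (ENSMUSG00000061723.18) held 14014 ± 1183 TPM and the fast calcium pump gene Atp2a1 (ENSMUSG00000030730.12) 12242 ± 82.6 TPM. The fast regulatory light chain gene Mylpf held 12241 ± 1309.8 TPM. Myh4 (ENSMUSG00000057003.12, chromosome 11, 67238029 to 67260446), the myosin heavy chain of type 2B fibres, held 11408 ± 748 TPM. Aldoa, the muscle aldolase, held 10957 ± 301 TPM, and Tpm1, alpha-tropomyosin, 10523 ± 774 TPM.

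Further fast contractile genes in the top 20 were Myl1 at 9370.1 ± 388 TPM, Tnni2 at 7510.0 ± 707 TPM, Tnnc2 at 4433 ± 41.8 TPM, Actn3 at 4269 ± 73.9 TPM and Mybpc2 at 2257 ± 256.04 TPM. Pvalb, a calcium buffer of fast fibres, held 7197 ± 184 TPM. The giant sarcomere genes Ttn and Neb held 3894 ± 819 and 3316 ± 250.03 TPM, and the Z-disc gene Tcap 1667 ± 123 TPM. The glycolytic genes Gapdh and Eno3 held 4515 ± 454 and 3043 ± 157 TPM, and Pygm, muscle glycogen phosphorylase, 3698 ± 372 TPM. These 20 genes held 37.3% ± 1.30 of all nuclear protein-coding TPM. Of 22028 annotated protein-coding genes, 9828 reached 1 TPM in both animals.

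**Figure D1:**
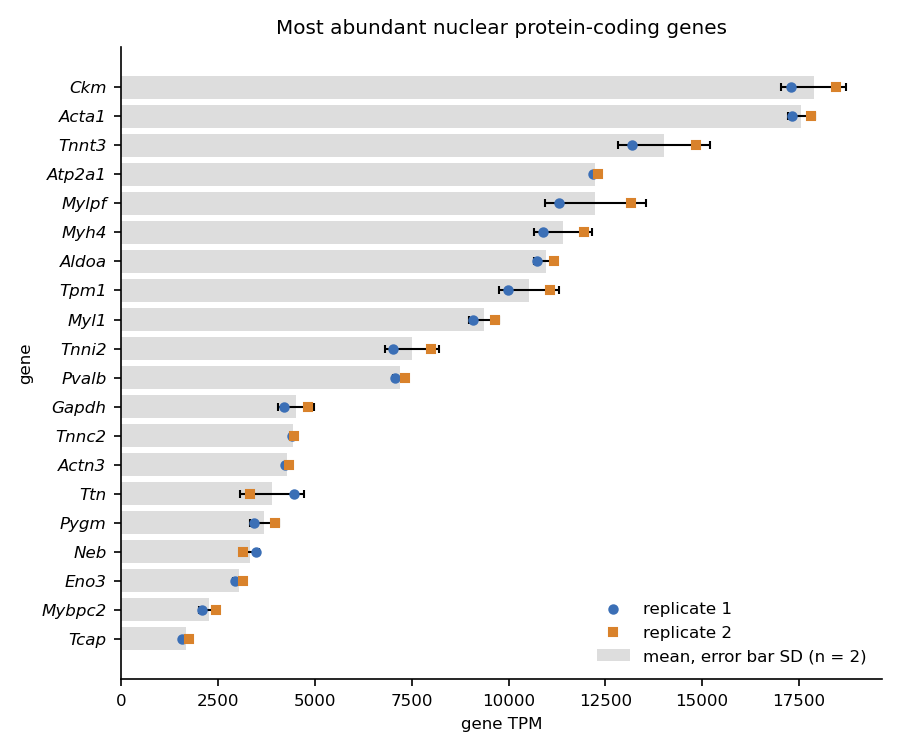
Gene TPM (horizontal axis) of the 20 most abundant nuclear protein-coding genes; bars are means of 2 animals, error bars SD, and points the single animals. Ckm leads at 17876 TPM, and Ttn is the gene whose animals lie farthest apart in relation to its mean.

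The muscle was dominated by fast fibre isoforms. Myh4 held 88.5% ± 1.55 of summed myosin heavy chain TPM (SD, n = 2). The fast genes Myh1 of type 2X fibres and Myh2 of type 2A fibres held 5.39% ± 0.316 and 3.52% ± 0.583, and Myh7 of slow fibres 1.69% ± 0.532. Embryonic Myh3 and perinatal Myh8, expressed in developing muscle, held 0.0139% and 0.409%. The extraocular Myh13 held 0.00876%, the cardiac Myh6 0.276%, Myh7b 0.00997% and the nonmuscle Myh14 0.138%. In replicate 1 Myh6 had 1896 counts at 43.9 TPM, against 6647 counts at 50.9 TPM for Myh8. The Myh6 share therefore rests on shorter transcripts and is uncertain. Only 69.6% of the 31-base words of Myh4, 62.1% of those of Myh1 and 67.2% of those of Myh2 occurred in no other gene, so the split between these neighbours is uncertain.

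Fast members exceeded slow members in each of 11 isoform pairs, with a median log2 ratio of 5.41 ± 0.50, or 42.4-fold. The calsequestrin pair Casq1 to Casq2, calcium buffers of the sarcoplasmic reticulum, had the largest ratio at 7.12 ± 0.37. It was followed by troponin T (Tnnt3 to Tnnt1) at 6.54 ± 0.62, troponin I (Tnni2 to Tnni1) at 6.31 ± 0.70 and the calcium pumps (Atp2a1 to Atp2a2) at 6.09 ± 0.49. Myosin heavy chains (Myh4 to Myh7) had 5.75 ± 0.49, and the light chains 5.41 ± 0.50 (Mylpf to Myl2) and 5.33 ± 0.39 (Myl1 to Myl3). Lower ratios were found for troponin C (Tnnc2 to Tnnc1) at 4.66 ± 0.46 and the calsarcins (Myoz1 to Myoz2) at 4.01 ± 0.57. The smallest were alpha-actinin (Actn3 to Actn2) at 3.60 ± 0.33 and myosin-binding protein C (Mybpc2 to Mybpc1) at 2.85 ± 0.31. In 11 of 11 pairs the ratio was larger in replicate 2, whose median was 5.76 against 5.06.

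**Figure D2:**
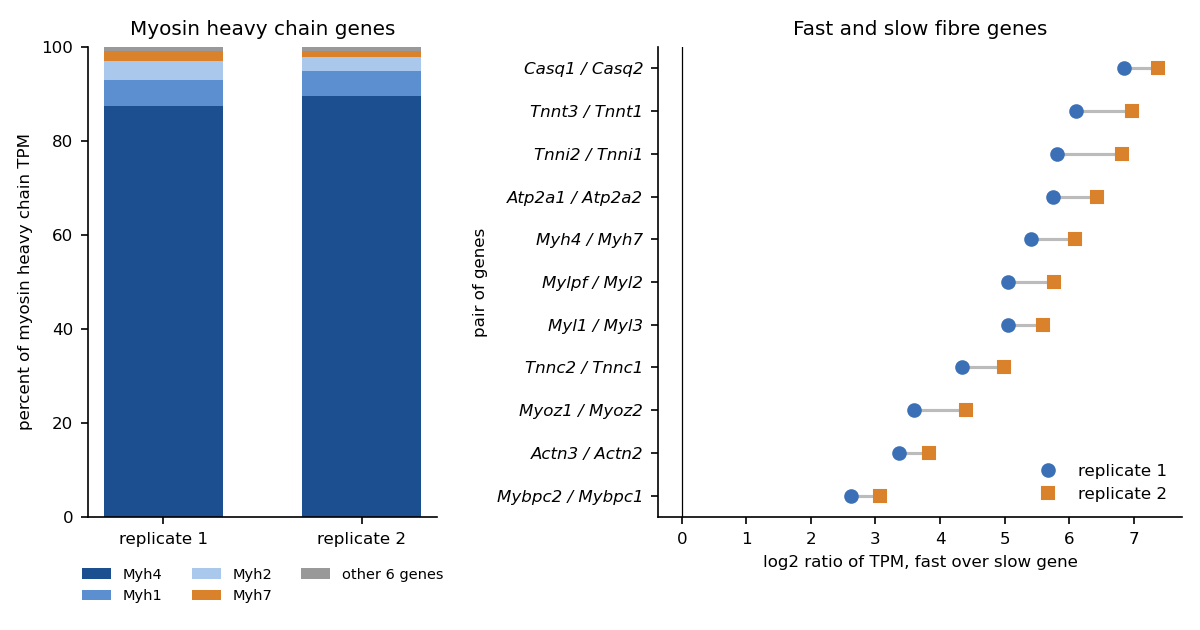
Left, stacked bars of the percent of summed myosin heavy chain TPM held by each gene in each animal; right, log2 ratio of fast over slow gene TPM for 11 isoform pairs, with a point per animal joined by a line. Myh4 holds 87.5% in replicate 1 and 89.6% in replicate 2, and every pair lies farther right in replicate 2.

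Energy metabolism genes were expressed at high levels. The 22 genes of glycolysis and glycogen had a median of 402 ± 27.6 TPM and the 40 nuclear-encoded respiratory chain genes one of 333 ± 3.34 TPM, with Atp5b, a subunit of ATP synthase, at 1473 ± 51.2 TPM. The citric acid cycle list (18 genes) had a median of 161 ± 4.69 TPM. Fatty acid uptake and oxidation (24 genes) had a median of 90.6 ± 6.09 TPM, with Fabp3, a fatty acid carrier, at 371 ± 76.3 TPM. Among phosphocreatine and adenylate genes, Ak1 held 768 ± 12.3 TPM and Ampd1 637 ± 1.07 TPM. Cytosolic ribosomal protein genes (34 genes) had a median of 186 ± 14.1 TPM.

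Excitation-contraction coupling genes (18 measured) had a median of 181 ± 9.45 TPM. Ryr1, the calcium release channel, held 968 ± 33.8 TPM and Trdn, which anchors calsequestrin, 548 ± 9.12 TPM. Sln, a peptide inhibitor of the calcium pump, held 0.195 ± 0.0495 TPM. The dystrophin glycoprotein complex (17 genes) had a median of 34.3 ± 0.467 TPM, with Sgca at 113 ± 1.29 TPM. Muscle transcription factors (25 genes) had a median of 24.0 ± 1.12 TPM, led by Mef2c at 191 ± 19.7 TPM and Tead1 at 113 ± 0.757 TPM. Myokine and growth control genes (16 genes) had a median of 5.55 ± 0.661 TPM. Among them the growth inhibitor gene Mstn held 27.0 ± 1.56 TPM, and Smox, a polyamine oxidase, 116 ± 20.5 TPM.

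Most marker lists of other cells had medians far below those of fibre genes. The fibroblast list had a median of 7.63 ± 0.283 TPM, with Gsn at 137 ± 19.1 and the matrix gene Dcn at 73.1 ± 3.59 TPM. Endothelial markers had a median of 6.61 ± 0.933 TPM, led by the water channel Aqp1 at 70.6 ± 15.3 TPM, and pericyte and smooth muscle markers one of 7.79 ± 2.80 TPM. Adipocyte markers had a median of 5.22 ± 0.548 TPM, satellite cell markers 1.45 ± 0.124 TPM, tendon markers 1.19 ± 0.339 TPM and Schwann cell and nerve markers 0.800 ± 0.0141 TPM. Macrophage and myeloid markers had a median of 0.353 ± 0.0884 TPM. The lymphocyte, skin and liver medians were 0.00, 0.00 and 0.0075 TPM, and those of bone and brain neurons 0.10 and 0.125 TPM. Exceptions were Ighm, an immunoglobulin heavy chain, at 62.0 ± 14.4 TPM, and Camk2a of the neuron list at 199 ± 7.39 TPM. Des of the satellite cell and pericyte lists, also a fibre gene, held 1081 ± 42.2 TPM, and Car3 of the adipocyte list 346 ± 41.1 TPM. Erythroid markers had a median of 28.1 ± 0.247 TPM, with Hbb-bs at 93.1 ± 6.24 TPM. The cardiac list had a median of 0.875 ± 0.0778 TPM, with Myl2, also expressed in slow fibres, at 292 ± 68.4 TPM.

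RNA without coding function took a large part of TPM and a smaller part of counts. Nuclear protein-coding genes held 43.4% ± 0.442 of TPM and 78.0% ± 1.46 of counts, and the annotation class of the signal recognition particle RNAs 32.2% ± 2.74 and 4.65% ± 0.716. The signal recognition particle RNA genes Rn7s1 and Rn7s2 (chromosome 12, starting at 69159295 and 69361182) each held 157978 ± 13800 TPM. Their values were identical, and 0.00% of their 31-base words were unique, so they form 1 measurement. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 held 62476 ± 11235 and 38436 ± 7614 TPM. Gm28437, a mitochondrial-like pseudogene on chromosome 1, held 14359 ± 1660.2 TPM with no unique 31-base word, so its reads cannot be placed. The mitochondrial genome held 14.5% ± 1.97 of all TPM. Another 4.48% ± 0.316 lay on 4 mitochondrial-like pseudogenes of chromosome 1, Gm28437 among them, so the mitochondrial share may be larger. The 13 mitochondrially encoded protein genes had a median of 2431 ± 28.2 TPM, led by mt-Co1 at 13269 ± 603 TPM, of whose 31-base words 36.1% were unique.

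Transcript usage was compared in 5832 genes. The same transcript was dominant in both animals in 5254 of them, or 90.1% (exact 95% interval 89.3 to 90.8%), and the median dominant share was 68.8%. The interval treats genes as independent draws, which they are not, and measures neither counting error nor spread between animals. Myh4-201 held 100% of Myh4 TPM, Atp2a1-201 99.9% ± 0.0138, Acta1-201 99.4% ± 0.0113, Ryr1-202 97.2% ± 0.456 and Tpm1-205 96.8% ± 0.662. Intermediate shares belonged to Aldoa-203 at 60.1% ± 1.70, Tnnt3-224 at 57.9% ± 2.47, Pkm-202 at 51.5% ± 0.469 and Neb-202 at 21.2% ± 0.224. The 2 quantifications named the same dominant transcript in 4385 of 5394 genes, or 81.3%. For Ckm they named Ckm-201 (58.2% ± 0.512) and Ckm-202 (50.6%), for Myl1 Myl1-202 (76.3% ± 1.66) and Myl1-207 (80.1%), and for Pfkm Pfkm-205 (80.8% ± 0.436) and Pfkm-201 (72.8%). Ttn and Tpm2 also differed in this way. The second quantification kept Acta1-201 and Tpm1-205 dominant but at 78.1% and 65.3%, so these 2 shares and the isoforms of the 5 genes named differently remain uncertain.

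The animals were compared gene by gene. The most abundant genes differed little, while Lars2, the ribosomal RNA-like Gm42418 and the heat shock and slow fibre lists were higher in replicate 1, and vessel marker lists were higher in replicate 2. Of 9515 genes with a mean of 100 or more counts, 96.6% lay within 1.5-fold, the median absolute log2 ratio was 0.12, and 88 were at least 2-fold apart. Of those 88, 55 were higher in replicate 1 and 33 in replicate 2, and 47 and 20 of them met the same ratio and count limits in the second quantification. An exact binomial test on counts called 2987 of 14095 tested genes beyond counting noise (Benjamini-Hochberg), 1492 higher in replicate 2 and 1495 in replicate 1. That even split follows from the scaling, since total counts gave 4285 genes with 83.3% higher in replicate 2, and spike-ins 4929 with 12.8%. An assumed biological variation of 0.1 left 290. Pearson's r across genes, which are not independent replicates, was 0.980. The test compares these 2 libraries, not conditions, and no difference between them has a replicate check. At high counts it also calls small ratios, so the number of called members of a list follows their expression level as well as their ratios. Against the trimmed mean scaling used, total counts moved the median of all tested genes by 0.11 on the log2 scale and spike-ins by −0.15, so ratios (replicate 2 over replicate 1) are relative to that scaling.

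**Figure D3:**
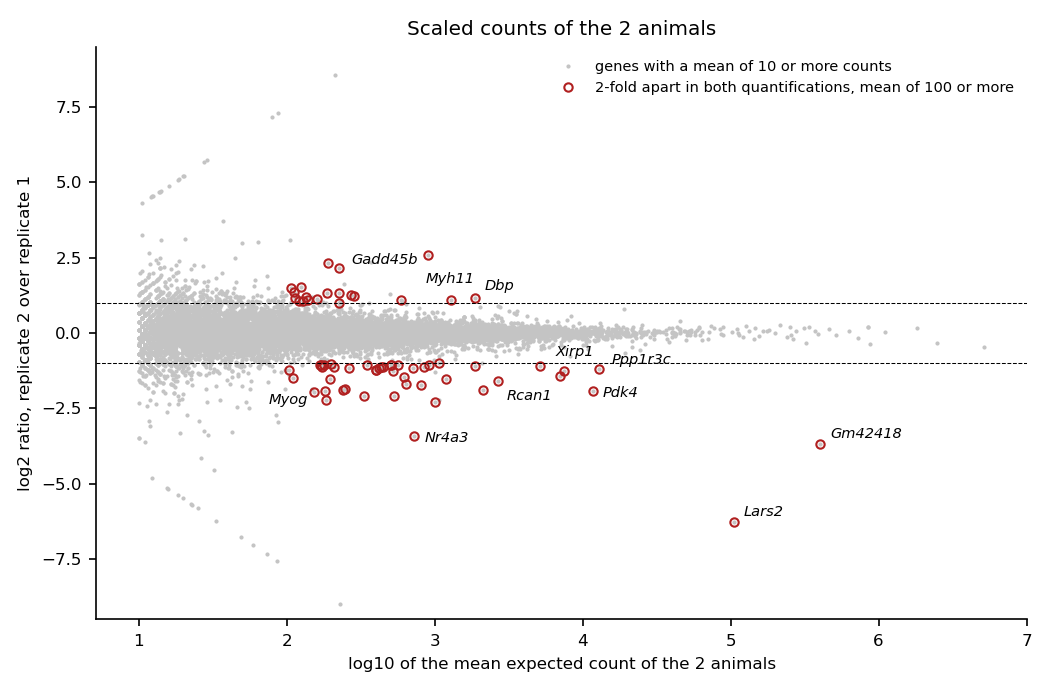
Log2 ratio of scaled counts, replicate 2 over replicate 1, against log10 of the mean count per gene; dashed lines mark 2-fold, and circles the genes 2-fold apart in both quantifications. Lars2 and Gm42418 lie at −6.27 and −3.70, below all other circled genes.

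Lars2 (chromosome 9, 123366927 to 123462666), which encodes mitochondrial leucyl-tRNA synthetase, was 77.1-fold higher in replicate 1, with 206159 against 2966 counts. Its excess lay on the transcript Lars2-209, while the coding Lars2-201 had a log2 ratio of −0.75, and −0.11 in the second quantification. Gm42418 (chromosome 17, 39846958 to 39848788) was 13.0-fold higher in replicate 1, with 735980 against 62919 counts. Of the nuclear ribosomal RNA list, Gm42418, CT010467.1 (−2.23) and Gm26917 (−0.32) were higher in replicate 1 and made up all 3 tested members (3 adjusted over the list alone). Nr4a3, an orphan nuclear receptor induced by exercise, was 10.7-fold higher in replicate 1 (1315 and 135 counts). The cytokine signalling inhibitor Cish, at −2.10, and Myog, a myogenic transcription factor, at −1.95, were also higher there. So was Pdk4, a kinase that restrains glucose oxidation (−1.92, 18048 and 5308 counts). Slc25a25, a mitochondrial ATP and phosphate carrier, had −1.90, the stress factor Atf3 −1.89 and Nfil3, a repressor in the clock, −1.74. Hspa1a and Hspa1b, inducible heat shock proteins, had −2.11 and −1.87, but only 34.6% and 32.0% of their 31-base words were unique.

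Genes higher in replicate 2 included Gadd45b, a stress-responsive gene, at 4.49-fold. Grip2 and Dach1 were 2.84-fold and 2.85-fold higher, and Tnfaip3, an inhibitor of inflammatory signalling, 2.55-fold. Ciart, a circadian repressor, was 2.51-fold higher, the gap junction gene Gja1 2.49-fold, Fmo2 2.40-fold and Rin2 2.34-fold. Ccdc3 and Pck1, the latter a gluconeogenic enzyme gene, were 2.29-fold and 2.26-fold higher. Vessel and fat markers were higher in the same library, with Cfd of adipocytes, Myh11 of smooth muscle and Kcnj8 of pericytes at log2 ratios of 1.14, 1.09 and 1.07. Zc3h11a appears under 2 gene identifiers with opposite ratios (−2.30 and 2.58), and its neighbour Zbed6 had 1.29 but 0.52 in the second quantification. Gvin1 had −1.92 with 0.344% of its words unique, so all of these share reads and are uncertain.

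Slow fibre protein genes were higher in replicate 1 as a group. Of 16 tested, 14 were called higher in replicate 1, 0 higher in replicate 2 and 2 were not called (14 adjusted over the list alone), and the median log2 ratio was −0.56. Csrp3, a Z-disc mechanosensor, had −1.45, Tnni1 −0.77, Tnnt1 −0.68, Myh7 −0.57 and Myl2 −0.51. Fast fibre protein genes had a median of 0.13, which turned negative under spike-in scaling, with 15 of 16 called higher in replicate 2 and Myh2 (−0.21) higher in replicate 1 (16 adjusted over the list alone). Of these Mybpc2 had 0.26, Tnni2 0.22 and Tnnt3 0.20, while the abundant Atp2a1 and Tnnc2 were called at only 0.043 and 0.050. Both medians lay outside the central range of random lists matched on expression (percentiles 0.00 and 100), and stayed outside after a transcript length and GC trend was removed, at −0.57 and 0.10.

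Fatty acid genes were higher in replicate 1, with 15 of 24 called, none called the other way and 9 not called (15 adjusted over the list alone), and a median of −0.12. Ucp3, a mitochondrial carrier induced by fatty acids, had −1.11 and Fabp3 −0.39. Glycolysis and glycogen genes had a median of 0.13, negative under spike-in scaling, with 16 of 22 called higher in replicate 2 and 2 higher in replicate 1 (20 adjusted over the list alone). Among these Pkm had 0.25, Pygm 0.21 and Gapdh 0.17. Cytosolic ribosomal protein genes had a median of 0.08, negative under spike-in scaling, with 17 of 34 called higher in replicate 2 (17 adjusted over the list alone). Rps14 had 0.27 and Rpl11 0.43. The ribosomal protein median fell inside the random range once the length and GC trend was removed, and the other medians did not.

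Heat shock, immediate early and denervation lists had medians higher in replicate 1. Of 19 heat shock and chaperone genes, 15 were called higher in replicate 1, 0 higher in replicate 2 and 4 were not called (16 adjusted over the list alone), with a median of −0.30. The constitutive Hspa8 had −0.48, and the small heat shock proteins Hspb6 and Cryab −0.30 and −0.23. Of 25 immediate early genes 9 were called higher in replicate 1 and 3 in replicate 2 (12 adjusted over the list alone), with a median of −0.21. Nr4a3 and Atf3 led the first set, while Jun (0.49) and Nr4a1 (0.31) were higher in replicate 2. Denervation and regeneration genes had a median of −0.17, with 5 of 18 called higher in replicate 1 and 1 in replicate 2 (7 adjusted over the list alone). Among them Myog had −1.95, the histone deacetylase gene Hdac4 −0.51 and Myh8 0.22. Atrophy and proteolysis genes had a median of −0.07, positive under total count scaling, with 10 of 27 called higher in replicate 1 and 3 in replicate 2 (13 adjusted over the list alone). Foxo1, which drives protein breakdown, had −0.95, and Cebpb −0.70.

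Markers of vessels and fat were higher in replicate 2. Pericyte and smooth muscle markers had a median of 0.37, with 11 of 14 called higher in replicate 2 and 0 in replicate 1 (11 adjusted over the list alone). Tagln and Acta2, contractile genes of smooth muscle, had 0.78 and 0.37. Endothelial markers had a median of 0.26, with 10 of 18 called higher in replicate 2 and 2 in replicate 1 (12 adjusted over the list alone). Tie1, an endothelial receptor, had 0.76 and Aqp1 0.47, while Eng had −0.56. Adipocyte markers had a median of 0.22, with 8 of 17 called higher in replicate 2 and 2 in replicate 1 (10 adjusted over the list alone). Plin1, a lipid droplet protein, had 0.65, and Car3, also abundant in slow fibres, −0.21. Erythroid markers had a median of 0.21, with 4 of 6 called higher in replicate 2 (5 adjusted over the list alone). They included Hba-a1 (0.26) and Hbb-bs (0.17), of whose words 24.5% and 45.6% were unique.

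Clock genes moved in both directions, with 8 of 19 called higher in replicate 2 and 3 in replicate 1 (12 adjusted over the list alone) and a median of 0.09 that was negative under spike-in scaling. The clock output gene Dbp had 1.15, Bhlhe40 0.73 and Nr1d1 0.72, and Nfil3 −1.74. Histone genes had a median of 0.24, with 5 of 14 called higher in replicate 2 (7 adjusted over the list alone). The most abundant, Hist1h1c, had 0.34. The largest ratio, 5.22 of Hist2h2aa1 at 0 and 40.3 counts, was only 0.064 in the second quantification and is uncertain. Small structural RNAs had a median of 0.17, with 5 of 11 called higher in replicate 2 and 1 in replicate 1 (6 adjusted over the list alone). Rn7s1 had 0.21, and Rn7s2, which forms 1 measurement with it, is counted as a separate member in these numbers. Nuclear and muscle long noncoding RNA lists had medians of −0.17 and −0.18, with 4 members of each called higher in replicate 1 and 1 in replicate 2 (5 adjusted over the list alone in each). Neat1, the paraspeckle RNA, had −0.52 and 2310065F04Rik −0.40. Reference genes had a median of 0.08, negative under spike-in scaling, with 7 of 16 called higher in replicate 2 and 2 in replicate 1 (11 adjusted over the list alone). Eef1a1 had 0.34. Removing the length and GC trend brought the structural RNA, long noncoding RNA and reference gene medians inside the random range.

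**Figure D4:**
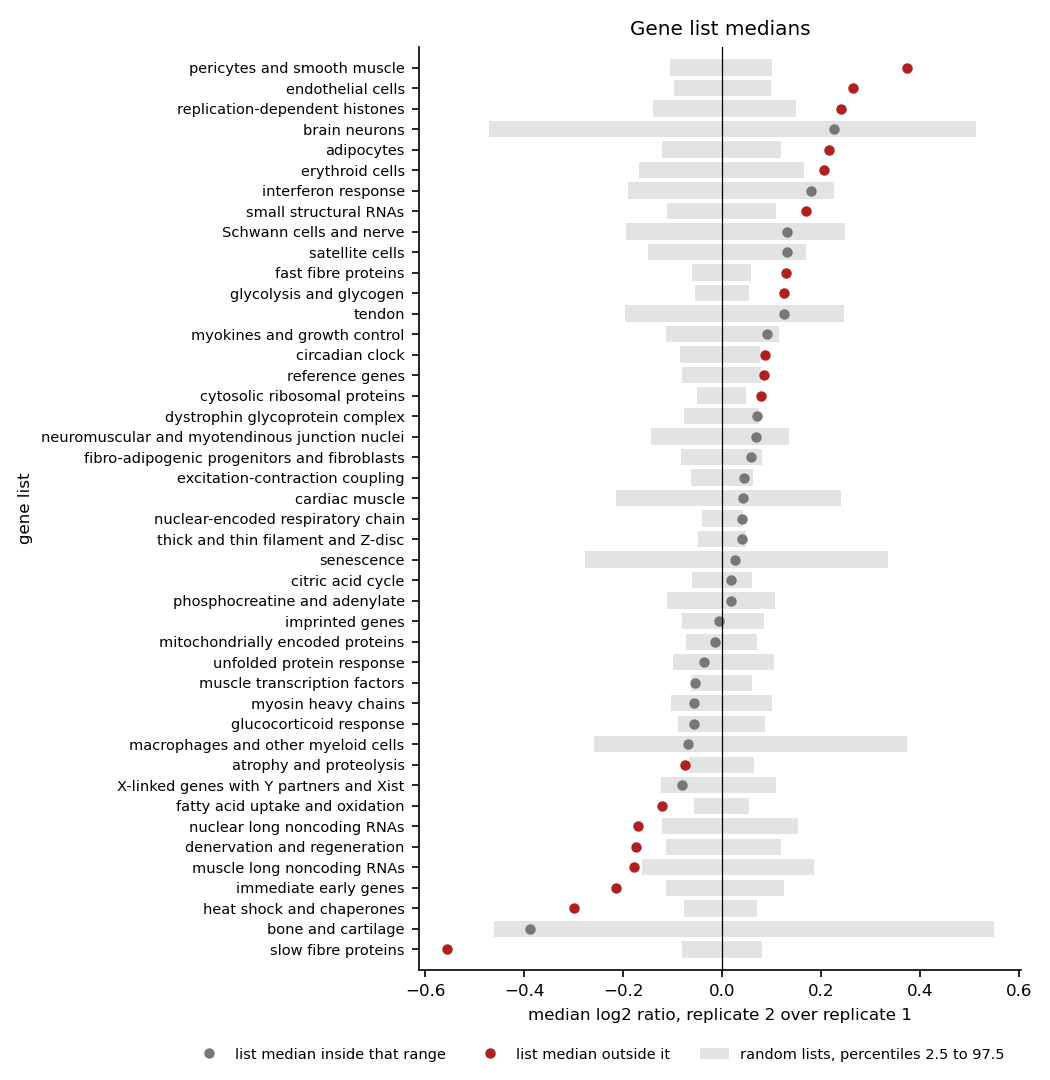
Median log2 ratio (replicate 2 over replicate 1) of each of 44 gene lists, with bars for the central 95% of 10000 random lists matched on expression. Slow fibre proteins lie lowest at −0.56 and pericytes and smooth muscle highest at 0.37; fast fibre, glycolysis, ribosomal protein, clock and reference gene medians turn negative under spike-in scaling, and the atrophy median positive under total counts.

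Some lists share members, such as Pfkm and Gpd1 (fast fibre and glycolysis) and H19 and Meg3 (both long noncoding RNA lists). They are therefore not independent observations. In all, 19 of 44 lists with 5 or more tested members lay outside the random range. The atrophy, adipocyte, erythroid, clock, histone, noncoding RNA and reference gene lists fell inside it under at least 1 alternative with the second quantification, a higher count minimum or the mean in place of the median. The remaining 25 lay inside it and are given without a direction. Thick and thin filament and Z-disc genes had a median of 0.04, with 14 called higher in replicate 2 and 12 in replicate 1 (26 of 27 adjusted over the list alone). In this list Xirp1, which encodes an actin-binding repeat protein, had −1.25, Ttn −0.46 and Tpm1 0.18. Excitation-contraction coupling and dystrophin complex genes each had 8 called higher in replicate 2 and 1 in replicate 1 (11 and 9 adjusted over the list alone), with medians of 0.04 and 0.07. Muscle transcription factors had 4 and 12 (16 adjusted over the list alone) and a median of −0.06, with Ppara at −1.15, and lay outside the range once the length and GC trend was removed. Myosin heavy chains had 3 and 3 (6 adjusted over the list alone). Respiratory chain genes had 10 and 1 (13 adjusted over the list alone), citric acid cycle genes 4 and 1 (5), phosphocreatine genes 2 and 2 (4) and mitochondrially encoded proteins 3 and 6 (9). Myokines had 5 and 2 (7), the unfolded protein response 1 and 4 (7), the glucocorticoid response 4 and 6 (10) and the interferon response 1 and 0 (1).

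Among cell type lists inside the random range, satellite cell markers had 5 called higher in replicate 2 and 2 in replicate 1 (10 adjusted over the list alone), with Sdc4 at −0.91 and Notch3 at 0.68. Fibroblast markers had 5 and 4 (9 adjusted over the list alone), with Gsn at 0.32 and Mfap5 at −0.72, and tendon markers 3 and 0 (3), with Fmod at 0.42. Junction nuclei markers had 1 and 3 (7 adjusted over the list alone), Schwann cell and nerve markers 1 and 0 (1) and myeloid markers 0 and 0 (0). Cardiac genes had 0 and 2 (2 adjusted over the list alone), bone and cartilage 0 and 1 (1), brain neurons 2 and 0 (2) and senescence genes 1 and 0 (2). With fewer than 5 tested members, the lymphocyte list had Ighm called higher in replicate 2 (1 adjusted over the list alone), the liver list Cyp2e1 (1), and the skin list 0 (0).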

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

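The tests of ribosomal RNA motifs in Lars2 and Gm42418 and of clock phases were chosen only after the result was seen. Reads of phiX, a bacteriophage genome used as a sequencing control, lay outside the main measurement and above the limit of 3 counts that a count of 0 allows. It held 85 counts in replicate 1 and 76 in replicate 2. The labels name 1 group, so the design gives no biological explanation to test.

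Lars2 and Gm42418 were far higher in replicate 1. A search for 31-base words shared with 357 annotated ribosomal RNA transcripts or Gm42418 placed 0.00% of the Lars2 excess on such transcripts, but none of those annotated holds the conserved 28S motif, so the search had nothing to find and decided nothing. Among 141767 annotated transcripts a 15-base motif of 28S ribosomal RNA occurred only in 2 of Lars2, which held 99.997% of its excess (93.5% in the second quantification) but also 99.7% of its replicate 2 counts, and Gm42418 held an 18S motif. The test of more Lars2 messenger RNA had no transcript to set apart and returned the fold of the whole gene, 77.1, while the coding Lars2-201 had log2 ratios of only −0.75 and −0.11, and transcripts without the motif held 15 and 9.55 counts. Ribosomal RNA carried into 1 library may account for both genes. In neither quantification did the coding Lars2-201 show a gap near that of the gene. As far as the division of reads holds, this argues against a rise of that size in the coding transcript. The second quantification gave Lars2-205, which lacks the motif, 31677 and 671 counts, where the first gave 0 and 0. A missing 15-base motif does not exclude other 28S sequence, so Lars2-205 decides nothing. The division of reads between transcripts is uncertain, and neither explanation was settled.

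Of the 88 genes at least 2-fold apart, 21 did not meet the ratio and count limits in the second quantification. A median of 13.6% of their 31-base words was unique, against 99.5% in 200 random genes and 99.8% or more in those 2-fold apart in both quantifications, and 14 of the 21 lay under 50%. Reads shared between near-identical genes may therefore produce many of these gaps, such as those of Gm14288, Gm5559 and Zbed6. The 7 genes over 90%, such as Csrnp1 (−1.01 and −0.98) and Sntb1 (1.02 and 0.93), had absolute ratios of 0.79 to 1.02 in the second quantification and so lay near the limit there. Id1 (−1.02) and Gm14760, at a mean of 3.94 counts, stayed 2-fold apart there and missed only the count limit. Among genes 2-fold apart in both, 4 of 47 higher in replicate 1 and 2 of 20 in replicate 2 also lay under 50%. Agreement of the quantifications therefore does not exclude shared reads.

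Under both quantifications 47 genes were at least 2-fold higher in replicate 1 and 20 in replicate 2. A trend on transcript length and GC content is too small to account for them, since median ratios of length and GC classes ran from −0.096 to 0.085. After its removal 100% of the 47 and 100% of the 20 stayed at least 1.5-fold higher, which a trend of that size could hardly have changed. For the genes of replicate 1 another share of muscle fibres was tested by asking for a change of about 2-fold in sarcomere genes. Their median was 0.039 (quartiles −0.15 and 0.15). That test cannot decide, because fibre genes are the most abundant and ratios are relative to the scaling. Another fibre share need not move sarcomere genes so far. The list also mixes fast and slow genes. Slow fibre genes had a median of −0.56 (quartiles −0.65 and −0.40), so another share of slow fibres stays open. More vessel and fat tissue in replicate 2 stays open, because the 48 pooled markers had a median of 0.25 (quartiles 0.010 and 0.49) and 3 of the 20 genes (Cfd, Kcnj8 and Myh11) are such markers. For the clock genes another hour of dissection may be a candidate explanation, with day-peaking genes (median 0.15) 0.83 above Arntl, Npas2 and Clock (median −0.68), though most of that gap lay in these 3 genes, of which only Arntl was beyond counting noise.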

How the results depend on the processing

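Scaling the lists by total counts or spike-ins and removing the length and GC trend from them were chosen after the data were seen, the other alternatives earlier. Of the main results, 46 of 60 values stayed close to the reported one. For numbers of genes called or 2-fold apart, close meant a total within 1.5-fold, whatever the split between the animals. The count beyond counting noise (2987) became 4929 with spike-ins as library size, 12.8% of them higher in replicate 2, and 290 with an assumed variation of 0.1. Total counts gave 4285, of which 83.3% were higher in replicate 2, against 49.9% as reported. Both splits follow from the moved centre. Genes 2-fold apart (88) became 604 at a mean of 10 and 33 at a mean of 500 counts, since other numbers of genes entered, and the share higher in replicate 2 (37.5%) became 55.6% with total counts and 21.1% with spike-ins. Detection at 5 TPM left 6168 genes. Counts in place of TPM moved the top 20 share to 43.3% and the mitochondrial share to 12.2%. The second quantification gave a Myh4 share of 86.3%, a summed fast fibre TPM of 78714 (reported 89832), a spike-in share of 0.246% and a transcript usage agreement of 87.4%. Over nuclear protein-coding genes only the fast sum was 206710.0 TPM, by its smaller denominator. Agreement was 85.7% from 1 TPM and 95.7% from 50 TPM. Except where a construction is named, the cause was not tested. Without 1 animal, detected genes ranged from 10096 to 10106, the top 20 share from 36.4 to 38.2%, the mitochondrial share from 13.1 to 15.9%, the Myh4 share from 87.5 to 89.6%, the pair median from 5.06 to 5.76, the fast sum from 86179 to 93486 TPM and the spike-in share from 0.257 to 0.308%. Transcript usage agreement needs both animals and has no such value. Of single genes and lists, 493 values stayed, 100 moved, 13 became stronger, 15 weaker and 8 reversed. Spike-ins reversed the fast fibre (−0.020), glycolysis (−0.024), ribosomal protein (−0.072), clock (−0.063) and reference gene (−0.065) medians, and total counts the atrophy median (0.038). The mean in place of the median reversed the reference genes (−0.022), and removing the trend the structural RNAs (−0.052). Between 15 (trend removed) and 20 lists lay outside the random range, and at least 14 of them were shared with the reported 19. Depth limits genes under 10 counts.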

Other observations

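No test in this part was chosen after a result was seen. Imprinted genes, expressed from 1 parental copy in at least some tissues, ranged widely. Alleles were not separated, so whether 1 or both copies were expressed in this muscle is not known. Of 42 measured, 24 reached 1 TPM in both animals, led by Gnas, a G protein subunit, at 575 ± 11.7 TPM and H19, a growth-restraining noncoding RNA, at 116 ± 2.38 TPM. Between the animals 4 of 33 tested were called higher in replicate 2 and 3 in replicate 1 (7 adjusted over the list alone). Impact had a log2 ratio of −1.07 and Igf2 one of 0.55, the latter with 38.1% of its 31-base words unique. Y-linked genes were led by Ddx3y at 26.3 ± 1.88 TPM and Eif2s3y at 18.5 ± 0.622 TPM, and 0 of 4 tested were called (0 adjusted over the list alone). Their X-linked partners were higher, with Usp9x at 83.8 ± 5.44 TPM and Ddx3x at 53.7 ± 4.96 TPM, and 1 of 6 tested was called higher in replicate 2 and 3 in replicate 1 (4 adjusted over the list alone). Xist, which silences 1 X chromosome in females, held 0.045 ± 0.0495 TPM.

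Cell cycle genes were near the floor, with 3 of 16 at 1 TPM in both animals, led by Pcna at 8.60 ± 0.552 TPM, and 0 called (0 adjusted over the list alone). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 had log2 ratios of −0.38 and −0.34 and were both called (2 adjusted over the list alone). Replication-dependent histone genes, whose messages usually but not always lack a poly(A) tail, were led by Hist1h1c at 91.0 ± 13.7 TPM and Hist1h4h at 59.7 ± 7.58 TPM. Malat1, a nuclear noncoding RNA, held 590 ± 20.6 TPM.

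Single genes differed between the quantifications. mt-Co3 had a log2 ratio of 0.80 in the gene table and −0.24 in the second quantification, with 0.133% of its words unique. mt-Atp8 held 1553 ± 336 TPM in the first and 0.939 TPM in the second, and Rprl3, a small structural RNA, 347 ± 92.8 and 0.00 TPM. Across all genes the quantifications correlated at 0.899 in replicate 1 and 0.901 in replicate 2. Across protein-coding genes these values were 0.978 and 0.980, and 97.4% of genes lay within 2-fold. Spike-ins took 0.283% ± 0.0362 of counts, with 388 gene counts per spike-in count in replicate 1 and 323 in replicate 2.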
